A study of Homo sapiens with 24 samples.

How the data were processed

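RNA-seq was run on macrophages sorted from synovium, the tissue that lines the joints. Per the labels' protocols, rheumatoid arthritis (RA) tissue came from ultrasound-guided biopsies and osteoarthritis (OA) tissue from joint replacements, so disease, way of sampling and joint were confounded. The tissue was digested to single cells, and cells carrying CD45, CD11B, HLA-DR and CD206 but neither CD15 nor CD1c were collected by flow cytometry. Libraries were made with a low-input full-length cDNA kit and a tagmentation kit and sequenced on an Illumina instrument. The series held 24 libraries, 9 OA and 15 RA. The labels placed 5 OA and 4 RA libraries in batch 1, 4 OA and 5 RA in batch 2, and 6 RA in batch 3. Group and batch were taken from the labels.

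The deposited table held whole-number counts per gene for 57905 Ensembl gene IDs, and the authors also deposited FPKM values for the same genes and libraries. The submitters' processing notes name bcl2fastq, TopHat2, HTSeq and the genome build hg19. The annotation and the counting options are not given in the sources used here. Over 486 genes checked, the deposited FPKM equalled the count divided by the library total and by 1 length per gene, with a relative spread of at most 3.63e-06 percent, so the FPKM hold no information beyond the counts and a fixed length. Over 27672 genes that length had a median of 1.95 times the longest transcript in GENCODE v29 (12773 against 1875 bp for GAPDH), so the FPKM are not values per transcript length, and a filter of at least 1 FPKM is a stricter one than on that scale. Every row carried an Ensembl gene ID. Genes of the Y chromosome, XIST and TSIX (485 rows) were left out of all steps, which left 57420 rows. Gene symbols came from the table. Gene type, and the transcript length used in 1 check, came from the GENCODE v29 annotation, in which 52338 of the IDs were found. No coordinates are given because that annotation is on another build.

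Low-input amplification without molecular identifiers makes counts of a gene non-independent, so depth alone does not set the precision of a value. Tagmented cDNA keeps no strand, so reads of overlapping antisense genes cannot be told apart, and reads of near-identical gene copies can be split or dropped in counting. This affects MRC1 and MRC1L1, CCL4 and CCL4L1, the metallothioneins and the HLA genes, whose values are uncertain for that reason. Total counts per library ran from 8.69 to 68.5 M (M, mega). No pair of libraries within a group agreed within counting noise: the lowest chi-square per degree of freedom was 39.4 over 36 OA pairs and 113 over 105 RA pairs.

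RA was compared with OA by the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with TMM scaling, the filterByExpr filter by group, batch and group in the model, all 24 libraries, and a Benjamini-Hochberg adjusted p below 0.05. The tests were two-sided. Log2 fold changes are RA minus OA, their SE is the fold change over the square root of F, and group levels are TMM-scaled counts per M (CPM) with SD. Levels of the sort genes, sums over lineage genes, counts of genes at 1 CPM and the group means beside the interaction are in CPM of the total counts, without TMM scaling. A difference of the RA effect between batches 1 and 2 was tested as an interaction in the libraries of these batches, and the difference between batches by both batch terms together. 39 gene lists, 24 of pathways and macrophage states and 15 of markers of other cell types, were fixed before the data were examined, and the 36 with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. The same lists were tested with an estimated correlation and with fry, which asks whether the members of a list move one way on balance, or change in either direction. The 3 lists not tested were markers of NK cells, erythroid cells and adipocytes. Similarity of libraries was the mean Pearson correlation of log2 CPM between libraries of the same group and batch, and it, depth and detected genes were compared by exact permutation of the group labels within batches 1 and 2.

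The rule for named genes was also fixed before the data were examined. It took the sort genes PTPRC, ITGAM, HLA-DRA, MRC1, FUT4 and CD1C. It took the 12 largest rises and 12 largest falls among passing genes with a mean of at least 5 CPM, the same sign in batches 1 and 2 fitted apart, and a symbol that is not a clone, LOC or pseudogene-style name, or, where none passed in a direction, the 8 with the smallest p as values. It also took up to 4 passing members of each list, or 2 members as values where none passed. Some genes that the rule takes are not reported here.

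After the data were examined, 6 RA libraries were put in doubt: 1 with HLA-DRA below 10% of the median, and 5 with fewer than 9000 genes at 1 CPM. All comparisons were run again on the remaining 18 libraries (9 OA, 9 RA), with the naming rule applied anew, and this set was chosen after seeing the data. A transcript-length correction took a loess trend of log count on transcript length (span 0.5) out of each library. Other alternatives were RLE size factors, DESeq2 1.42.0, limma-voom with sample weights, no filter and a stricter one, other batch terms, single batches, detected genes as a covariate, 2 surrogate variables (sva 3.50.0), limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 1 or no filter, and each library left out in turn.

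The tests were checked on simulated counts drawn from the real means and totals, with 200 genes changed by 2-, 4- or 8-fold. For the 24 libraries at their own dispersion, none of the changed genes was recovered at any of these folds over 13847 genes. With the dispersion of the 18 libraries, the same 24 libraries gave back 1.52%, 37.3% and 89.8%. For the 18 libraries, 6.25%, 46.8% and 80.0% were recovered over 13549 genes, with 1 false call among 82. For the interaction between batches, none was recovered over 13689 genes at the observed dispersion. A list of changed genes passed in the simulations of 24 and of 18 libraries, and 0 of 30 unchanged lists passed in either. Genes were drawn independently of each other there. In the 24 real libraries the estimated correlation within a list ran from 0.0392 (plasmacytoid dendritic cell) to 0.746 (mitochondrial genome). The simulation therefore does not show how often unchanged lists of correlated genes pass.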

Results

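The data were gene counts of 24 libraries of macrophages sorted from the synovium of donors with RA, an autoimmune inflammatory joint disease, and of donors with OA, a degenerative joint disease. There were 15 RA and 9 OA libraries in 3 batches, and batch 3 held RA libraries alone. Total counts had a median of 13.4 M (M, mega) in OA (11.5 to 68.5 M) and 14.0 M in RA (8.69 to 57.7 M). The comparison of the groups asked how macrophages of RA and OA synovium differ.

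The genes behind the sort served as a check of the labels, with levels in CPM of the total counts, without TMM scaling. PTPRC, which encodes CD45, averaged 655 ± 316 CPM in RA (SD, n = 15) and 293 ± 126 CPM in OA (SD, n = 9), and HLA-DRA averaged 14800 ± 8400 and 9850 ± 2670 CPM. ITGAM, which encodes CD11B, averaged 145 ± 134 CPM in RA and 197 ± 75.9 CPM in OA, and 3 libraries held less than 1 CPM of it. MRC1, which encodes CD206, averaged 12.3 ± 22.8 and 9.95 ± 7.24 CPM, low levels for which reads shared with its copy MRC1L1 leave the value uncertain. FUT4, which makes the CD15 sugar, averaged 5.21 ± 5.27 CPM in RA and 7.87 ± 3.01 CPM in OA. CD1C had a median of 1.74 CPM in RA and 2.96 CPM in OA, but its highest value over the RA libraries was 1890 CPM. Among macrophage genes outside the sort, CD14 averaged 2180 ± 1220 CPM in RA and 1670 ± 305 CPM in OA, C1QA 1370 ± 916 and 3060 ± 711 CPM, and CD68 0.949 ± 1.00 and 0.535 ± 0.302 CPM, with less than 1 CPM of CD68 in 17 of 24 libraries. In 1 RA library HLA-DRA was below 10% of the median over all libraries, and 5 further RA libraries held 3381 to 6907 genes at 1 CPM, against 9263 to 14987 in the 18 others. The 3 libraries with less than 1 CPM of ITGAM and the one with 1890 CPM of CD1C were among these 6, and the highest CD1C of the 18 others was 43.4 CPM. 1 RA library kept among the 18 also stood apart, with C1QA at 0.99 CPM. Its mean log2 CPM, minus the OA mean, was -4.79 for tissue-resident macrophage genes (next lowest of the RA libraries among the 18 -1.39). It was 6.19 for endothelial, 3.86 for mural and 4.29 for chondrocyte markers. The next highest of the RA libraries among the 18 were -0.703, 0.0504 and -0.0781, and the highest OA libraries 1.11, 1.24 and 1.24.

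In all 24 libraries, 8 gene lists passed with a preset correlation between genes. Of 29 measured interferon gamma response genes, 24 had a higher and 5 a lower fitted level in RA, with a median log2 fold change of 0.92 (camera adjusted p = 0.000151). All 17 genes of MHC class II presentation had a higher fitted level (median 0.53, adjusted p = 0.0291), as did 15 of 20 infiltrating monocyte genes (median 1.38, adjusted p = 0.0131). The metallothionein list holds genes of metallothioneins, which bind zinc and copper, and of zinc transporters. It had a lower fitted level in 9 of 12 members (median -1.78, adjusted p = 0.000124), and fibroblast markers in 14 of 17 (median -0.82, adjusted p = 2.19e-05). Tissue-resident synovial macrophage genes had a lower level in 13 of 21 members (median -0.67, adjusted p = 0.00410). Heat shock genes had a higher level in 15 of 19 (median 0.42, adjusted p = 0.00917), and glycolysis and hypoxia genes a higher level in 21 of 30 (median 0.31, adjusted p = 0.0220). These were 8 of 36 lists, and none passed with an estimated one, where the lowest adjusted p was 0.689. By fry none of these 8 passed, with adjusted p from 0.216 for fibroblast markers to 0.944 for glycolysis genes, and oxidative phosphorylation was the 1 list called (lower, adjusted p = 0.0164). Leaving out each library in turn ended the call of MHC class II presentation in 9 of 24 fits (adjusted p up to 0.151, without RA replicate 10). It ended the call of monocyte genes in 3 fits and of tissue-resident and glycolysis genes in 2 each. The other 4 lists passed in all fits. With detected genes as a covariate 16 lists passed, but 3 of the 8 among them. Fibroblast (0.0777), monocyte (0.693), glycolysis (0.0899) and heat shock genes (0.140) lost the call, and MHC class II presentation turned to lower without passing (0.140). Adjusted over the list alone, MT1A and MT2A among the metallothioneins, PRG4 among the fibroblast markers and FABP4 in the lipid and lysosome list were lower, and no member of the other 6 passing lists passed.

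At the level of single genes, 1 of 14255 tested genes passed in edgeR's quasi-likelihood test of the 24 libraries. FGF20, a fibroblast growth factor gene, fell in RA, from 2.25 ± 1.27 CPM in OA (SD, n = 9) to 0.0202 ± 0.0464 CPM (SD, n = 15), a log2 fold change of -6.45 (SE 1.03, edgeR adjusted p = 0.00568). It lay below the lowest OA library in all 15 RA libraries, which together held 7 counts of it against 611 in OA. It is named outside the rule, after its value was seen, because its mean is below 5 CPM. At an unadjusted p below 0.05 there were 449 genes, 203 higher and 246 lower, and DESeq2 called 71 genes. Without RA replicate 10 no gene passed (482 at an unadjusted p below 0.05), and without OA replicate 6, RA replicate 4 or RA replicate 12 the number was 2, 2 and 3.

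Genes with the smallest p that did not pass are given as values. BEGAIN, named for a protein of synapses, had the largest positive fold change among these, 7.68 (SE 1.56, edgeR adjusted p = 0.121), and lay above the highest OA library in 11 of 15 RA libraries. RA libraries of batch 2 held 33645 counts of it, and 6012 without the library with low HLA-DRA, when the fold change was 6.45. Without RA replicate 12 BEGAIN passed (adjusted p = 0.0316). It also passed in DESeq2 (1.57e-09) and in edgeR with no filter (9.92e-06), with no batch term (0.026) and in batches 1 and 2 only (0.0254). Without the 5 RA libraries with few genes it passed as well (edgeR adjusted p = 0.0307), as it did without all 6 RA libraries in doubt (0.017). The remaining settings did not call it, among them limma-voom, with a fold change of 0.754, and log2(FPKM + 1), with 1.84. TNFSF14, the cytokine LIGHT, had 4.52 (SE 1.32), SLAMF7 4.46 (SE 1.48) and TXLNB 3.96 (SE 1.29). These 3 leaned on 1 library: without RA replicate 2 they had 2.55, 3.22 and 2.47. The lymphoid receptor LY9 had 3.15 (SE 1.03), ATP13A3 3.02 (SE 0.95), MICAL2 2.85 (SE 0.92) and the glucose transporter SLC2A3 2.38 (SE 0.73). On the other side stood MT1A with -6.16 (SE 1.502), the fatty acid binding protein FABP4 with -5.65 (SE 1.605), the cholesterol 25-hydroxylase CH25H with -5.23 (SE 1.26) and PRG4, the joint lubricant lubricin, with -4.88 (SE 1.38). SCRG1 had -4.35 (SE 1.38), the chemokine gene copy CCL4L1 -3.89 (SE 1.15), SHROOM1 -3.07 (SE 0.98) and MT2A -2.71 (SE 0.87). FABP4, MT1A, SCRG1 and MT2A lay below the OA median in 15 of 15 RA libraries.

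Members of the passing lists in the 24 libraries were likewise short of the threshold one by one. WARS, an interferon gamma response gene, had a log2 fold change of 1.67 (SE 0.80) and HLA-DQA1 1.67 (SE 0.90). VCAN had 1.73 (SE 0.75) and CD300E 2.03 (SE 1.00) among the monocyte genes, and HSPA8 0.76 (SE 0.44) and DNAJB4 1.55 (SE 0.90) among the heat shock genes. RNASE1 had -1.73 (SE 0.72) and NUPR1 -2.19 (SE 1.07) among the tissue-resident genes, MMP3 -3.45 (SE 1.25) among the fibroblast markers, and HK2 1.91 (SE 1.22) among the glycolysis genes.

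Without the 6 RA libraries in doubt, 726 of 13878 genes passed, 440 higher and 286 lower in RA. In the 24 libraries 131 of these had an unadjusted p below 0.05 and 1 passed. These 18 libraries were chosen after seeing the data, only RA libraries were left out, and the common dispersion was 0.512 against 1.59 in all 24. Of the 5 left out for few genes, 4 were in batch 3, and leaving those out bore mainly on the spread and not on the fold changes. The RA libraries kept were 3 in batch 1, 4 in batch 2 and 2 in batch 3. The number of passing genes rested on single libraries: it was 392 without OA replicate 4, 293 without OA replicate 6, 365 without OA replicate 7 and 1136 without RA replicate 4. With the number of detected genes as a covariate, which was lower in RA, 128 genes passed, 121 of the 726 among them, and 50 of 90 named genes were weaker. Fitted alone, batch 2 gave 472 genes, and batch 1, with 5 OA and 3 RA libraries, gave 0 in edgeR with 2067 at an unadjusted p below 0.05. DESeq2 called 2004 genes and limma-voom 4333. The balance of directions depended on the method: 1984 were higher and 2349 lower in limma-voom, 430 and 635 with log2(FPKM + 1), 911 and 1604 with 2 surrogate variables, and 366 and 106 in batch 2 alone.

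Among the 12 largest rises in the 18 libraries by the naming rule, the lymphoid receptor gene LY9 rose from 1.43 ± 1.52 CPM in OA to 13.3 ± 14.96 CPM in RA (log2 fold change 3.46, SE 0.75, edgeR adjusted p = 0.0145) and lay above the OA median in 9 of 9 RA libraries. The integrin subunit ITGAL rose by 2.69 (SE 0.75), and the myeloid receptor CD300E rose by 2.37 (SE 0.58), from 42.2 ± 40.4 to 192 ± 106 CPM. PTPRC, a gene of the sort, rose by 1.46 (SE 0.27, edgeR adjusted p = 0.00762), by 0.61 in batch 1 and 2.28 in batch 2. SLC2A3 rose by 2.26 (SE 0.45) from 79.1 ± 43.0 to 413 ± 256 CPM, MICAL2, an actin-oxidising enzyme, by 2.29 (SE 0.44) and ATP13A3, a transport ATPase, by 2.87 (SE 0.37, adjusted p = 0.000686), and these 3 lay above the OA median in 9 of 9. The other rises of the rule were BEGAIN at 5.24 (SE 1.18, above the OA median in 6 of 9), GFOD1 at 3.00 (SE 0.78), GPRC5B at 2.98 (SE 0.84), CELSR1 at 2.77 (SE 0.75), CERKL at 2.38 (SE 0.39) and NBEAL2 at 2.34 (SE 0.55).

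Of the 12 largest falls in the 18 libraries by the naming rule, 5 were metallothioneins. MT1G fell by 5.93 (SE 1.57) on the log2 scale, MT1A by 5.52 (SE 1.28), and MT1X by 4.11 (SE 0.98). MT2A fell by 3.88 (SE 0.80) and MT1E fell by 3.80 (SE 1.02). MT2A went from 1925 ± 1452 CPM in OA to 184 ± 165 CPM in RA (SD, n = 9 each, edgeR adjusted p = 0.0123), and all 5 lay below the OA median in 9 of 9 RA libraries. CH25H, which makes 25-hydroxycholesterol, fell from 112 ± 106 to 6.17 ± 8.45 CPM (log2 fold change -4.97, SE 0.92, adjusted p = 0.00794). SCRG1 fell by 4.60 (SE 1.08), the matrix metalloproteinase MMP3 fell by 3.83 (SE 0.94), and the secreted phospholipase PLA2G2A fell by 3.81 (SE 1.01). CCL4L1 fell by 3.81 (SE 0.88) and the antimicrobial peptide gene DEFB1 fell by 3.60 (SE 0.93). MMP3 is on the fibroblast marker list, which was lower in the same libraries (15 of 17 members, median -1.08, camera adjusted p = 0.00162), but not with an estimated correlation (0.798), by fry (0.164) or with detected genes as a covariate (0.373).

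**Figure D1:**
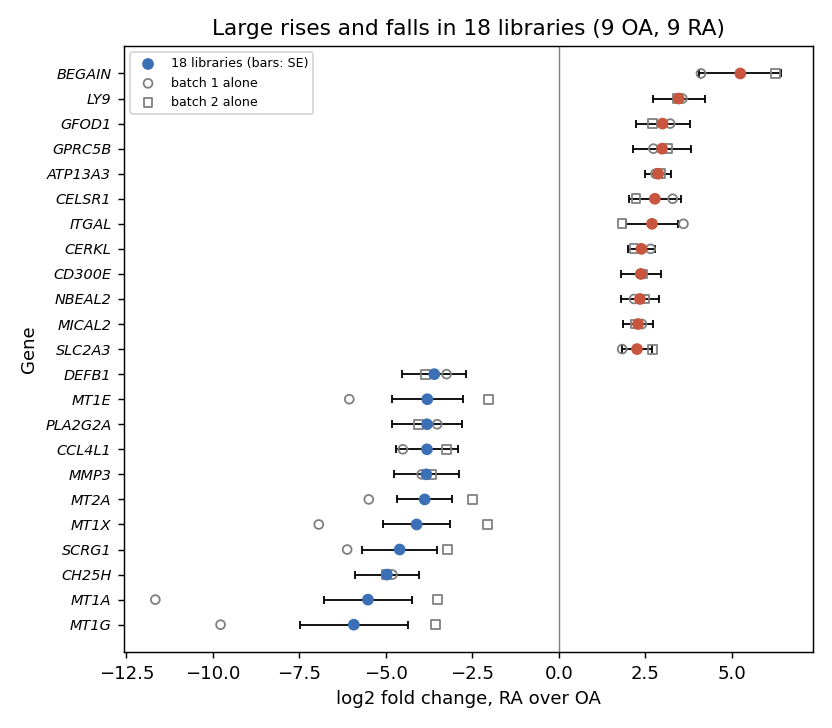
Log2 fold change of RA over OA (x axis) for the 12 largest rises and 11 of the 12 largest falls by the naming rule in 18 libraries (9 OA, 9 RA), with filled points and SE bars for the 18 libraries and open symbols for batch 1 and batch 2 fitted alone. The naming rule required the same sign in both batches. The batch 1 values of MT1A and MT1G rest on 0 and 58 counts over the 3 RA libraries of that batch, so their size is a fitted value and not a measured fold.

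Of the metallothionein list, which also holds genes of zinc transporters, 11 of 12 members had a lower fitted level in the 18 libraries (median -2.88, camera adjusted p = 0.000171). Of these 5 passed, and 6 passed adjusted over the list alone. Genes of the glucocorticoid response list were lower in 12 of 19 (median -0.26, adjusted p = 0.0254), with 3 passing and 4 adjusted over the list alone. This call was lost in 2 of 18 fits without 1 library (0.119 without RA replicate 3). TSC22D3, which encodes the glucocorticoid-induced leucine zipper, fell from 1171 ± 238 to 599 ± 223 CPM (log2 fold change -1.17, SE 0.23), CEBPD fell by 1.25 (SE 0.33) and the phosphatase gene DUSP1 by 1.10 (SE 0.25). With an estimated correlation both lists, like the other 34, had an adjusted p of at least 0.798, whereas fry found both to move down (adjusted p = 0.0334 and 0.0213). Both falls lay mostly in batch 1: the mean log2 CPM of the metallothionein list, minus the OA mean, was -3.96 in RA and 0.867 in OA there, and -1.89 ± 1.25 and -1.08 ± 1.63 (SD) in batch 2. For the glucocorticoid list it was -1.72 and 0.128, and -0.217 and -0.16. In batch 2 alone neither list passed (camera adjusted p = 0.199 and 0.320), and with detected genes as a covariate the glucocorticoid list did not (0.127).

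Of the interferon gamma response genes, 25 of 27 had a higher fitted level in the 18 libraries (median 1.29, adjusted p = 3.93e-06 in camera with the preset correlation), 5 passed, and 10 passed adjusted over the list alone. The mean log2 CPM of the list, minus the OA mean, was 0.452 ± 0.96 in RA and 0.252 ± 1.19 in OA in batch 1 (SD), and 1.14 ± 1.31 and -0.316 ± 0.167 in batch 2. CIITA, the regulator of MHC class II transcription, rose from 42.7 ± 23.7 to 110 ± 66.7 CPM (log2 fold change 1.69, SE 0.38), NLRC5, its class I counterpart, rose by 2.03 (SE 0.50), the guanylate binding protein GBP2 by 1.63 (SE 0.40) and APOL6 by 1.29 (SE 0.28). All 17 MHC class II presentation genes were higher (median 0.69, adjusted p = 0.000201), with CIITA passing, but the batches differed. This mean was 0.287 in RA and 0.29 in OA in batch 1, and 0.982 and -0.363 in batch 2. HLA-DRA itself had -0.09 in batch 1 and 0.93 in batch 2. Of 34 type I interferon genes 29 were higher (median 0.68, adjusted p = 0.0270), and MX2 rose by 1.66 (SE 0.31) and SAMD9 by 0.99 (SE 0.28); these 2 were also the count adjusted over the list alone. The list lost its call in 4 of 18 fits without 1 library (up to 0.665, without RA replicate 4), and its mean was lower in RA in batch 1 (-0.1 against 0.298) and higher in batch 2 (-0.134 against -0.372). With an estimated correlation the adjusted p of these 3 lists was 0.798, and fry did not find any of the 3 to move one way (adjusted p = 0.186, 0.180 and 0.556).

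Genes of oxidative phosphorylation fell as a group in the 18 libraries: 38 of 39 were lower (median -0.71, camera adjusted p = 2.82e-10; 0.798 with an estimated correlation), 18 passed, and 30 passed adjusted over the list alone. NDUFS5 fell by 1.02 (SE 0.19), UQCR10 by 1.26 (SE 0.25), UQCRQ by 1.08 (SE 0.24) and COX6C by 0.93 (SE 0.21), and fry gave an adjusted p of 0.0213. All 13 transcripts of the mitochondrial genome were lower (median -0.83, adjusted p = 0.000201; 0.798 with an estimated correlation), with MT-CO2 at -1.22 (SE 0.25) and MT-CO3 at -1.05 (SE 0.27) passing and 11 adjusted over the list alone. Ribosomal protein genes were lower in 46 of 54 (median -0.29, adjusted p = 0.0373; 0.915 with an estimated correlation), with RPL38 passing at -0.76 (SE 0.21) and none adjusted over the list alone. This list lost its call in 13 of 18 fits without 1 library (up to 0.353, without RA replicate 3). These are short transcripts, and over 13631 genes, which are not independent replicates, the fold change rose with transcript length (Spearman correlation 0.331). With the length trend of each library removed, oxidative phosphorylation remained lower (adjusted p = 0.0241, median -0.20), while the mitochondrial and ribosomal lists turned to higher without passing (adjusted p = 0.955 and 0.372), and 287 genes passed in place of 726.

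Infiltrating monocyte genes were higher in 15 of 20 members in the 18 libraries (median 0.90, camera adjusted p = 0.0465; 0.798 with an estimated correlation). CD300E and the matrix proteoglycan VCAN passed, VCAN with 1.78 (SE 0.45), and 3 members passed adjusted over the list alone. Without 1 library the list lost its call in 10 of 18 fits (up to 0.208, without RA replicate 5). Its mean log2 CPM, minus the OA mean, was lower in RA in batch 1 (-0.128 against 0.265) and higher in batch 2 (0.628 against -0.331). Tissue-resident genes did not pass as a list (adjusted p = 0.110), but NUPR1 fell from 514 ± 264 to 115 ± 111 CPM (log2 fold change -2.61, SE 0.55) and the ribonuclease RNASE1 from 9332 ± 3730 to 4311 ± 3487 CPM (-1.68, SE 0.45), with 3 lower adjusted over the list alone. Heat shock genes were higher in 16 of 19 (median 0.35, adjusted p = 0.00218; 0.798 with an estimated correlation), with HSPA1A at 1.04 (SE 0.28) and HSP90AB1 at 0.75 (SE 0.20). The mean of that list was -0.427 in RA and -0.311 in OA in batch 1, and 1.29 and 0.388 in batch 2. The glycolysis and hypoxia list did not pass in the 18 libraries (18 of 30 higher, adjusted p = 0.110), though SLC2A3 and the histone demethylase KDM3A (1.10, SE 0.28) rose.

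**Figure D2:**
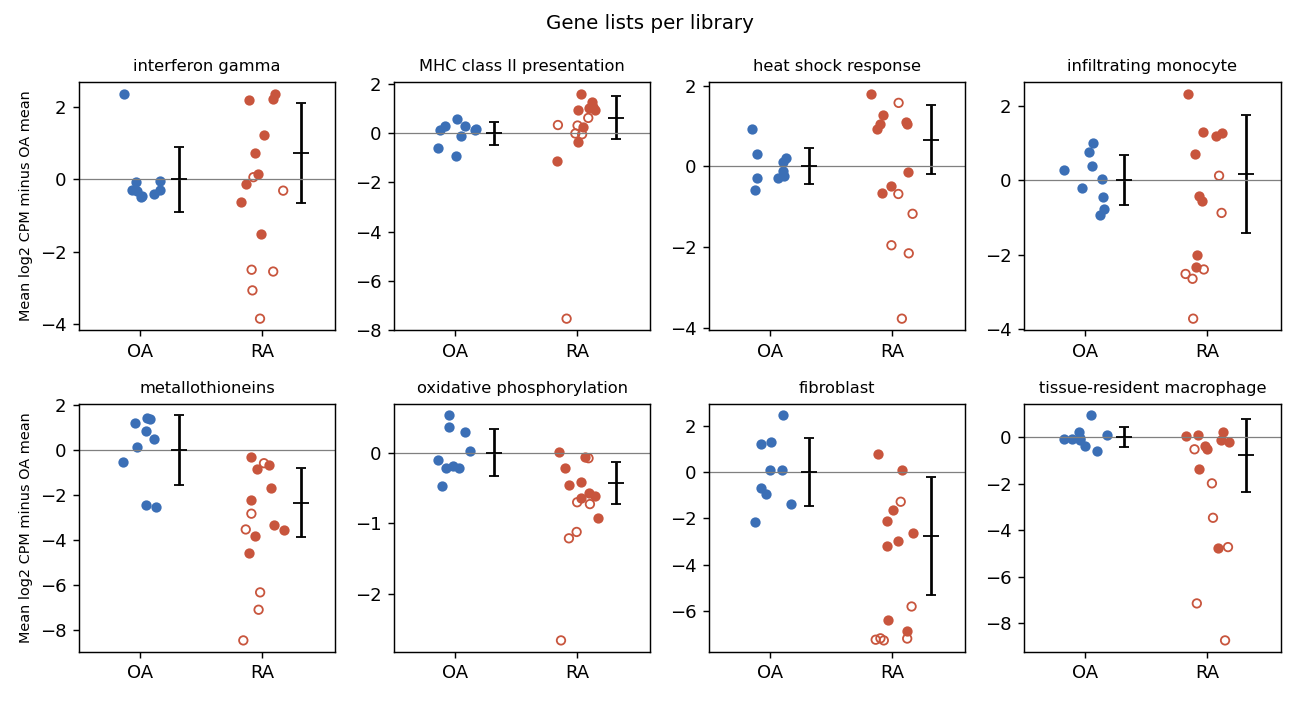
Mean log2 CPM of 8 gene lists per library, minus the OA mean (y axes), in 9 OA and 15 RA libraries; open circles are the 6 RA libraries left out of the set of 18, and bars give the mean and SD of OA and of the 9 remaining RA libraries. The mean of the metallothionein list lay below the OA median in 9 of 9 of these RA libraries, that of oxidative phosphorylation in 7 of 9, and that of MHC class II presentation above it in 7 of 9.

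Inflammatory and early response genes moved in both directions in the 18 libraries, and the batches differed. Mean log2 CPM of the immediate early list, minus the OA mean, was -0.979 in RA and -0.19 in OA in batch 1. In batch 2 it was 0.83 and 0.237. For the NF-kB list it was -1.88 and -0.0769 in batch 1, and 0.585 and 0.096 in batch 2. Both lists were among the 19 of 36 that fry called for change in either direction (adjusted p = 3.77e-09 and 0.00809), against 0 in the 24 libraries. Of 26 immediate early genes 12 were higher and 14 lower (camera adjusted p = 0.843). JUN, the AP-1 transcription factor, fell from 625 ± 159 to 199 ± 86.4 CPM (log2 fold change -1.82, SE 0.26, edgeR adjusted p = 0.00189) and lay below the lowest OA library in 9 of 9 RA libraries, whereas NR4A3 rose by 1.92 (SE 0.50); 4 rose and 6 fell adjusted over the list alone. Of 34 NF-kB and cytokine genes 16 were higher (adjusted p = 0.835). The cytokine oncostatin M, OSM, rose by 1.58 (SE 0.33) and NFKBIA, the NF-kB inhibitor, fell by 1.70 (SE 0.49), with 1 higher and 3 lower adjusted over the list alone. Of the chemokine list no member passed (adjusted p = 0.893), and CCL3 and CCL4 had -1.93 (SE 0.56) and -2.42 (SE 0.78). Complement factor D, CFD, fell from 1699 ± 572 to 482 ± 255 CPM (-2.10, SE 0.38, edgeR adjusted p = 0.00762) in a complement list that did not pass (adjusted p = 0.110; 2 higher and 3 lower adjusted over the list alone).

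Single members of further lists passed while the lists did not. The protease CTSK, on the osteoclast list (camera adjusted p = 0.341) and the matrix remodelling list (0.243), fell by 2.01 (SE 0.40), and 2 matrix genes and 1 osteoclast gene were lower adjusted over the list alone. TGFB3 fell by 3.52 (SE 0.89) among growth and repair factors (0.551), where it was also the 1 gene adjusted over the list alone. RA libraries held 52 counts of TGFB3 against 521 in OA, with 1 count in batch 1 and 41 in batch 2, so the size of its fall is uncertain. EDEM1 rose by 2.14 (SE 0.39) in the unfolded protein response list (0.130, with 3 higher adjusted over the list alone), and the sterol and cholesterol synthesis list did not pass (0.242). MCM5 rose by 0.92 (SE 0.26) in the cell cycle list (0.778, with 0 adjusted over the list alone), and BCL2L11 rose by 1.54 (SE 0.41) while BAX and GADD45B fell by 0.82 (SE 0.23) and 0.99 (SE 0.27) in the apoptosis list (0.768, with 1 higher and 3 lower). No member of the lipid and lysosome list passed (0.252), in which FABP4 had -4.95 (SE 1.505) and NPC1 1.47 (SE 0.43).

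Of the markers of other cell types, the fibroblast list was the one that passed in either set of libraries, in neither with an estimated correlation (adjusted p = 0.689 in the 24 and 0.798 in the 18). In the 18 libraries the lists of endothelial (camera adjusted p = 0.751), mural (0.893), T (0.843), B (0.357), plasma (0.907), neutrophil (0.550), mast (0.386), conventional dendritic (0.843), plasmacytoid dendritic (0.843), skeletal muscle (0.709) and chondrocyte (0.948) markers did not pass, and SERPINF1, on the plasmacytoid dendritic list, was the 1 member to pass, at -1.46 (SE 0.39). Levels varied widely in RA: the T cell gene IL7R averaged 79.3 ± 81.3 CPM in RA and 11.5 ± 20.2 CPM in OA, the plasma cell gene IGHG4 283 ± 798 and 14.0 ± 36.1 CPM, and the endothelial gene CDH5 26.1 ± 71.0 and 1.49 ± 1.22 CPM (n = 9 each). The latter values rest on 1 library each: without RA replicate 4 the log2 fold change of CDH5 went from 3.63 to 0.45, and without RA replicate 3 that of IGHG4 from 5.29 to -1.29. CDH5 lay below the OA median in 5 of 9 RA libraries. In the 24 libraries the 28 lists that did not pass had adjusted p from 0.0529, for the glucocorticoid response, to 0.916, for T cell and plasma cell markers. Camera compares a list with the other genes, and its direction differed from the sign of the median for the ribosomal (median -0.18, higher), chemokine (0.22, lower), cell cycle (0.20, lower), neutrophil (0.10, lower), T cell (-0.20, higher) and plasma cell (0.04, lower) lists. In the 18 libraries it differed for the chemokine list (median 0.55, lower), and the T cell list had a median of -0.29 and a mean of 0.11.

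Transcripts of cells outside the joint were found in part of the libraries and are given beside these results. The RA library with low HLA-DRA carried hepatocyte and melanocyte genes, with summed CPM of 4760 and 3810. In 9 other libraries, 8 of them in batch 2 and 1 in batch 1, the same genes stood at 3.61% to 19.9% of that level, and in the 14 others at no more than 0.0388%. The mean share in batch 2 was 15 ± 5.00% in 4 OA libraries and 10.0 ± 6.34% in 4 RA libraries. Subtracting that profile at each library's share gave 681 passing genes in the 18 libraries, 369 higher and 312 lower. It ended the calls of 9 named genes, GPRC5B, CELSR1, ITGAL, DEFB1, SAMD9, NLRC5, HSPA1A, HSP90AB1 and EDEM1 (adjusted p from 0.0548 to 0.0862), and of the type I interferon list (0.0552). The log2 fold changes of these genes stayed close to those given above. In that order they were 3.32, 3.045, 2.615, -3.76, 1.05, 2.105, 0.952, 0.8255 and 2.44. The lost calls thus do not show that the subtracted transcripts made these differences.

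The RA effect differed between batches 1 and 2 for 80 of 14021 genes in edgeR's test of the interaction, and all 80 had the lower fitted RA effect in batch 1. The collagenase MMP1 averaged 28.3 CPM in OA and 0 CPM in RA in batch 1, against 5.13 and 10.5 CPM in batch 2 (adjusted p = 0.00822). The growth factor FGF7 averaged 6.67 and 0 CPM in batch 1 and 1.36 and 0.98 CPM in batch 2 (adjusted p = 0.00860), and the homeobox gene HOXA9 1.77 and 0 against 1.72 and 2.90 CPM (adjusted p = 0.0121). Of the 80 genes, 59 had 0 counts over the 4 RA libraries of batch 1 and 76 had 3 or fewer, so the sizes of the fitted differences are no measured folds. Those RA libraries also held fewer detected genes, a median of 15480 against 24440 in OA, while batch 2 had 26010 and 26360. The test cannot tell this apart from an RA effect on the 80 genes. The RA mean of batch 2 includes the library with low HLA-DRA. Without the 6 libraries in doubt 92 genes passed, 65 of the 80 among them, and the RA means of MMP1, FGF7 and HOXA9 in batch 2 were 7.89, 0.649 and 1.59 CPM. DESeq2 called 256 genes and edgeR without a filter 12.

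Between batches, 1068 of 14255 genes differed in the 24 libraries, and 111 of 13878 in the 18. Leading genes in the 18 were CPS1, EFEMP1, PSAT1, DPPA4 and MLANA. The liver enzyme CPS1, the pluripotent cell gene DPPA4 and the melanocyte gene MLANA were higher in batch 2 than in batch 1, by 6.63, 3.99 and 4.97 on the log2 scale. Batch 2 held 8 of the 9 libraries with transcripts of cells outside the joint. Within RA libraries alone, 0 genes passed in edgeR of the 1998 that the filter left, with 77 at an unadjusted p below 0.05. With 1 group that filter kept genes counted in nearly all RA libraries. Genes found in 1 batch alone were thus left out before the test.

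RA libraries resembled each other less than OA libraries did. The mean correlation of log2 CPM between libraries of the same group and batch was 0.686 in RA and 0.946 in OA, a difference of -0.26 (two-sided exact permutation p = 0.0075 over 15876 splits). In batch 1 it was 0.527 in 4 RA and 0.939 in 5 OA libraries, and in batch 2 0.781 in 5 RA and 0.957 in 4 OA libraries. Without the libraries in doubt the means were 0.770 and 0.946 (exact permutation p = 0.0135 over 3920 splits). Between the 6 RA libraries of batch 3, which has no OA library to set beside them, the mean was 0.438.

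RA libraries also held fewer detected genes. The median number of genes with at least 1 count was 17030 in RA and 25400 in OA (difference -8364, two-sided exact permutation p = 0.0309), and at 1 CPM it was 12030 and 13610 (difference -1576, exact permutation p = 0.00346). The difference in median total counts was 0.60 M (exact permutation p = 1). By batch, the genes with at least 1 count were 15480 in RA and 24440 in OA in batch 1, and 26010 and 26360 in batch 2. Median total counts were 11.6 M in RA and 14.9 M in OA in batch 1, and 21.2 M and 12.95 M in batch 2. Of these 2 batches, the lower number of genes with at least 1 count thus lay in batch 1, at lower depth. In batch 2 the medians were close and the ranges overlapped, at greater depth in RA. At 1 CPM the median was lower in RA in both, 10650 against 13040 in batch 1 and 13250 against 14340 in batch 2. The RA medians over all libraries also include batch 3, whose RA libraries held 7909 to 21335 genes with at least 1 count, below the lowest OA library (21460). In the 18 libraries the RA median was 21340 (exact permutation p = 0.0255).

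**Figure D3:**
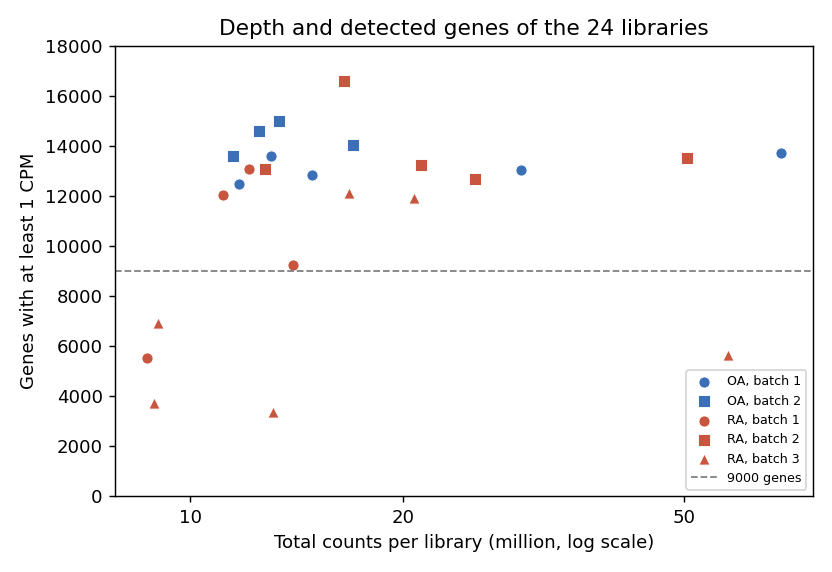
Genes with at least 1 CPM (y axis) against total counts per library in M (x axis, log scale) for 9 OA and 15 RA libraries, with 1 symbol per batch and a dashed line at 9000 genes. The 5 RA libraries under the line hold 3381 to 6907 genes at totals from 8.69 to 57.7 M, and 4 of them are in batch 3.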

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

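Of 126 sets of values in the 9 OA libraries, 4 held 1 library far from the others, where chance gives about 1 in 20; no explanation was weighed for these. OA replicate 3 had a log2 CPM of 6.38 for SLAMF7, with the next highest OA library at 2.66. OA replicate 8 had 6.47 for the immunoglobulin gene IGHG4, with the next highest at 2.35. OA replicate 2 had -0.885 for CCL4L1, with the next lowest at 2.70, and total counts of 68.5 M, with the next highest at 29.4 M.

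The RA effect on MME, which encodes the peptidase CD10, differed between batches by a fitted log2 value of 8.52 (batch 2 minus batch 1, edgeR adjusted p = 0.0406). It averaged 1.84 CPM in OA and 0 CPM in RA in batch 1, and 7.99 and 12.1 CPM in batch 2, so the fitted value depends on the prior count and is no measured fold. The RA value of batch 2 includes the RA library with low HLA-DRA. Without the 6 RA libraries in doubt, a set chosen after seeing the data, it was 4.39 CPM, below OA. The fitted difference between batches was then 7.71, of like size, and did not pass (edgeR adjusted p = 0.0564). Of 121 named genes, MME was the 1 that passed this test.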

How the results depend on the processing

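The set of 18 libraries with all its alternatives, and the fits without the library with low HLA-DRA or the 5 with few genes, were chosen after seeing the data; the other alternatives and the splits of the samples were fixed before.

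In the 24 libraries, 1 gene also passed with RLE, with detected genes as a covariate and without that library. It was 71 in DESeq2, 3902 in limma-voom with sample weights, 270 with no filter, 4 with no batch term, 4 with 2 surrogate variables and 25 in batches 1 and 2 only. It was 63 with log2(FPKM + 1), 55 with log2(FPKM + 0.1) and 156 with no filter on FPKM. In edgeR it was 0 with a stricter filter (169 at an unadjusted p below 0.05), 0 in batch 1 only (1087) and 0 in batch 2 only (1838). Leaving out 1 library gave 0 to 3 genes, with 0 without RA replicate 10, 2 without OA replicate 6, 2 without RA replicate 4 and 3 without RA replicate 12. It was 369 without the 5 libraries with few genes and 726 without these and the one with low HLA-DRA. The 8 passing lists became 5 in batch 1 (4 of the 8 among them), 16 with detected genes as a covariate (3), 14 with FPKM (6), 10 with no filter (5), 0 with an estimated correlation, and 6 to 11 without 1 library.

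In the 18 libraries, 726 genes became 2004 in DESeq2, 4333 in limma-voom, 2515 with 2 surrogate variables, 402 with no filter, 271 with no batch term, 128 with detected genes as a covariate, 472 in batch 2, 287 with the length trend removed, and 0 in batch 1 (edgeR, 2067 at an unadjusted p below 0.05). It was 293 to 1136 without 1 library: 392 without OA replicate 4, 293 without OA replicate 6, 365 without OA replicate 7 and 1136 without RA replicate 4. RLE, the stricter filter, batches 1 and 2, FPKM and subtraction gave 618 to 1065. Of the 726 genes, 1 changed sign in limma-voom and 0 with RLE and DESeq2. The 11 lists became 0 with an estimated correlation and 8 to 11 without 1 library.

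Directions reversed for single genes in limma-voom: in the 24 libraries CHAC1 had -1.13, MCAM -1.21, THEMIS -1.26, ELANE -1.21 and SOX9 -1.48, and in the 18 MCAM had -1.33 and THEMIS -1.38. Of the lists in the 24 libraries, immediate early genes (camera adjusted p = 0.0112) and conventional dendritic cells (0.0478) turned to higher with no batch term, and cell cycle genes (0.00810) with detected genes as a covariate. That covariate turned MHC class II presentation (0.140) and ribosomal proteins (3.83e-05) to lower, and ribosomal proteins were also lower in batch 2 (0.0205) and without the 6 libraries (0.0373). The endothelial list turned to lower without RA replicate 4 (range without 1 library 0.0189 to 0.592). In the 18 libraries, the NF-kB list was higher in batch 2 (0.0126), and removing the length trend turned the mitochondrial (0.955) and ribosomal (0.372) lists to higher.

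Without 1 library, the interferon gamma, heat shock, metallothionein and fibroblast lists passed in all fits of both sets, as did MHC class II, oxidative phosphorylation and the mitochondrial genome in the 18. In the 24, MHC class II lost its call without OA replicates 5 (0.0566) and 7 (0.0580) and RA replicates 1 (0.139), 2 (0.110), 3 (0.0808), 5 (0.0767), 8 (0.0512), 9 (0.101) and 10 (0.151). Monocyte genes lost it without RA replicates 2 (0.146), 5 (0.147) and 10 (0.0700), tissue-resident genes without 4 (0.0849) and 11 (0.157), and glycolysis without 1 (0.0850) and 11 (0.0721). In the 18, type I interferon genes lost it without OA replicate 5 (0.0507) and RA replicates 4 (0.665), 5 (0.103) and 10 (0.128), and glucocorticoid genes without OA replicate 5 (0.0531) and RA replicate 3 (0.119).

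The 80 genes of the interaction between batches became 12 with no filter and 256 in DESeq2, with 68 by RLE and 92 without the 6 libraries. The 1068 genes that differed between batches became 6279 with no filter, 111 without the 6 libraries and 0 in RA libraries only (edgeR, 77 at an unadjusted p below 0.05), where the filter left 1998 genes. The similarity difference ranged from -0.37 to -0.176. Unless a cause is given, the cause was not tested.

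Over 100 splits each, drawn and with the real one included, 2 gave at least the 80 genes of the interaction, with 97 in the highest other. That share lay under the bound of 5% set beforehand, but a drawn split exceeded the real count, so chance was not ruled out. For batches 1068 compared with 580 in the highest other (1 split), under the same bound. In 24 libraries 1 gene compared with 0 (1 split), but it was lost without RA replicate 10. In 18 libraries 726 compared with 1 (1 split), given that choice of libraries, which the splits do not repeat.

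On counts simulated at the real totals of the 24 libraries, 89.8% of 8-fold changes were recovered with the dispersion of the 18 libraries. With the dispersion of the 24 libraries 0% were recovered, so in the simulation the spread was enough to end recovery. Depth was not varied there, so whether depth also limited single genes was not tested.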

Other observations

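The tests of the lineage lists, of the 8 libraries of batch 2, of batch by Fisher's exact test and of thinned counts were chosen after the results were seen. So were the set of 18 libraries and the genes named in this part. The weighing of folds with the length trend removed was not set beforehand either. The other tests were written before.

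Among the genes with the smallest p in the 18 libraries, the actin-bundling gene LCP1 rose from 317 ± 157 to 1164 ± 388 CPM (log2 fold change 2.00, SE 0.27, edgeR adjusted p = 0.00153) and the lipid enzyme gene LPGAT1 from 23.8 ± 5.24 to 68.0 ± 20.8 CPM (1.70, SE 0.19, adjusted p = 0.000387), both above the highest OA library in 9 of 9 RA libraries. CSF2RB, the shared receptor chain of GM-CSF, IL-3 and IL-5, rose by 2.24 (SE 0.38), the transcription factor BACH1 by 1.90 (SE 0.28), and the kinase genes HIPK3 and MAPK14 by 1.57 (SE 0.22) and 1.22 (SE 0.19), each above the OA median in 9 of 9. PARP14 rose by 1.61 (SE 0.20) and lay above the OA median in 7 of 9. PLA2G16 fell from 101 ± 28.9 to 44.0 ± 35.3 CPM (-1.82, SE 0.23, adjusted p = 0.000686), the matrix gene EFEMP1 by 2.89 (SE 0.42) and PDK4, which restrains pyruvate oxidation, by 2.89 (SE 0.71).

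Complement C1q genes, APOE and TREM2, which mark macrophages, had lower fitted levels that did not pass. C1QA had a log2 fold change of -1.38 (SE 0.68, edgeR adjusted p = 0.251), C1QB -1.70 (SE 0.85), C1QC -1.27 (SE 0.51), APOE -1.90 (SE 0.93) and TREM2 -1.43 (SE 0.92), and TREM2 lay below the OA median in 9 of 9 RA libraries. Without RA replicate 4, the library with the lowest C1QA, C1QA had -1.14 (SE 0.28, adjusted p = 0.0193) and C1QB -1.46 (SE 0.42, adjusted p = 0.0406) and passed. C1QC had -0.97 (SE 0.30), APOE -1.62 (SE 0.85) and TREM2 -1.20 (SE 0.70), and without RA replicate 3 APOE had -2.89 (SE 1.21).

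A candidate explanation of the RA library with low HLA-DRA is RNA of a pool of cell lines in place of the sample: 4 of 4 lineage lists (hepatocyte, melanocyte, luminal breast epithelium and pluripotent cell) stood at least 10 times above the 14 libraries without these transcripts. Those 14 libraries were picked by their low hepatocyte and melanocyte sums relative to that library, which all but fixed the outcome for these lists. The other lists were not used in that choice. Their summed CPM was 5980 against at most 46.4 for luminal breast epithelium, and 438 against at most 40.1 for pluripotent cells. Another synovial cell type was set against the hepatocyte and melanocyte sum, at 2580 times the highest of those 14 libraries. The choice of the 14 fixed a ratio above 10, so this test could not decide. In the 8 other libraries of batch 2 that carried the transcripts, the lowest Spearman correlation with that library across 45 genes, which are not independent replicates, was 0.951, which may reflect its RNA or reads passing into them; the lowest over all 9 was 0.49, in the 1 library of batch 1, where the source stayed open. Expression by synovial cells would not follow the batch (Fisher's exact test p = 1.96e-05). No biological explanation was tested further.

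The step from few genes passing in 24 libraries to many in 18 was set against loss of transcripts in 5 RA libraries. By the rule set beforehand each of the 5 had to hold more ribosomal protein and oxidative phosphorylation genes at 0 counts than the highest of the 18. This was not met, as 3 of the 5 held any. The lowest of the 5 had 0 of 93 ribosomal protein and oxidative phosphorylation genes at 0 counts and the highest had 15, against 0 in each of the 18 libraries. The bound on the lowest library was a poor one, since these genes averaged at least 47.4 CPM in the 18 libraries and a lower yield would leave them above 0. For that reason the failed prediction does not decide the question. Thinned to 8.69 M counts, the highest of the 5 held 11242 genes and the lowest of the 18 held 12986. Their fewer genes were thus not a matter of depth alone. The 5 had been chosen for few genes at 1 CPM, a measure already scaled to depth, and the groups were not compared again on thinned counts. The thinning therefore does not decide whether depth had a part in the step from 24 to 18 libraries. Leaving out any 6 RA libraries did not give such numbers of passing genes, as 20 random sets of 6 gave at most 36 genes, with a median of 0.

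Fold changes rose with transcript length in the 18 libraries, and a length bias was weighed as a possible explanation. With each library's length trend removed, oxidative phosphorylation remained lower (camera adjusted p = 0.0241 at the preset correlation, median -0.71 before and -0.20 after). By the rule set beforehand, length was then not the whole cause of that shift. The removal was not tested with an estimated correlation, at which the list did not pass before it (camera adjusted p = 0.798). Of 713 called genes with a length, 36.5% were still called, below the bound set beforehand, which is the outcome predicted by length as the whole cause of the calls. That bound was on calls alone, and no rule was set beforehand for the folds. The median absolute log2 fold change was 1.16 before and 0.98 after, the median SE 0.27 and 0.26, and 710 kept their sign. Genes picked by their calls tend to keep sign and size, and the loess may leave part of a length trend. The folds therefore do not decide whether length was the whole cause of the calls. The RA minus OA difference in length slope was 0.251 in batch 1 and 0.261 in batch 2, a ratio of 1.04 (SE 0.30). By the rule set beforehand, a difference at least as large in batch 2 counts against lower library complexity in RA as its cause. That rule took no account of the SE, within which the batch 2 difference may also be the smaller. The ratio therefore did not decide.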
